A study of Mus musculus with 6 samples.

How the data were processed

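RNA was measured by sequencing of ribosomal-RNA-depleted libraries in 6 samples of mouse peritoneal macrophages, 3 treated with vehicle and LPS and 3 treated with trametinib and LPS. The authors deposited 1 table of counts, whole numbers of reads assigned to each gene in each library, with no normalization. Per the submitters' processing notes, the reads were handled with HISAT2 2.1.0, featureCounts 1.6.4, DESeq2 1.24.0 and R 3.6.0 on the mm10 genome build. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Values of close paralogs (the Bcl2a1, Gbp, Oas, Klra and H2 genes among them) and of genes that overlap on opposite strands are therefore less certain than those of single-copy genes.

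The table held 25354 gene entries, of which 310 repeated 1 of 205 identifiers with identical values. The repeats were removed, leaving 25044 genes, and gene positions and biotypes were taken from GENCODE mouse release M21 on mm10, in which 25033 of the identifiers were found. The other 11 were kept in the library totals. Library totals ran from 17453778 to 19648467 counts, a ratio of 1.13. Replicates of a group differed by a chi-square per gene of 5.98 to 28.1, where reads drawn from 1 pool would give about 1, and no library was a copy of another.

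Groups were taken from the labels. Genes were kept by filterByExpr, library sizes were scaled by TMM factors, and trametinib was compared with vehicle by the quasi-likelihood test of edgeR 4.0.16 (robust fit, group as the only term, 4 residual degrees of freedom). Adjusted p values are Benjamini-Hochberg values over all genes tested, and a gene passed at an adjusted p under 0.05. Log2 fold changes are trametinib over vehicle, and their standard error (SE) is the size of the log2 fold change divided by the square root of the F statistic. CPM are counts relative to the library size scaled by its TMM factor, given as mean ± SD. The p values measure the spread between these samples, because the labels do not say which animal each replicate came from. The sample information gives 3 mice for the study, so the 6 libraries cannot come from 6 different mice. Ratios of genes with 1 to 3 counts in a group carry an exact 95% interval, and such intervals cover counting error only. The share of counts on mitochondrially encoded genes was compared by an exact permutation test, two-sided.

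The replicate numbers are shared by the groups. Deviations from the group means correlated across genes at 0.339, 0.393 and 0.285 between libraries of the same number, and at −0.0724 to −0.223 between libraries of different numbers. The numbers may therefore pair the samples, a hint that comes from the data and not from the labels. The main comparison did not use this pairing, so its counts and p values are unpaired. The fit with the replicate number as a block was an alternative, and its values are given where it changed a call or moved a count by more than 1.5 times.

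The following were set before the data were examined: the design, the threshold, the alternatives (apart from those for gene families), 25 pathway lists, 11 marker lists and the rule for named genes. That rule takes the 8 highest and the 8 lowest log2 fold changes among genes past the threshold with a mean of at least 5 CPM, groups that do not overlap and a symbol that is not a predicted-gene or clone name. It also takes 16 genes whether changed or not, and up to 3 members of each pathway list with the smallest p. Not every gene that the rule takes is described. Other genes named below were chosen after their values were seen. The pathway lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 25 lists, and again with a correlation estimated from the data and with fry. Each list's members were counted as adjusted over all genes tested and as adjusted over the list alone. The marker lists cover macrophages, resident large peritoneal macrophages, neutrophils, eosinophils, mast cells, B cells, T and NK cells, dendritic cells, fibroblasts and mesothelium, nuclear-retained RNAs and mitochondrially encoded mRNAs. They were read as contents of the culture or RNA quality and had no set test. The gene Ighm, a B cell marker, was not in the table.

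The alternatives were DESeq2's median-ratio size factors in edgeR, TMM factors without the 10 most abundant and the mitochondrial genes, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, the replicate block, and leaving out each library in turn. The edgeR procedure was tested on simulated data with 200 genes changed by set folds among 11286, beside a small further set shifted to test camera. It recovered 23 of 48 genes changed 1.5-fold, 42 of 49 changed 2-fold, 48 of 49 changed 4-fold and 49 of 49 changed 8-fold, and called 22 of 10980 unchanged genes. R 4.3.3, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used, and BLAST 2.17.0 served to compare mitochondrial transcripts with annotated nuclear copies. No library was left out of the comparison.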

Results

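Macrophages were washed from the peritoneal cavity of wild-type C57BL/6 mice aged 8 weeks, 3 days after an injection of thioglycollate, an irritant that draws monocyte-derived macrophages into the cavity. Cells that adhered within 1 h were cultured for 24 h and then received vehicle (DMSO) or 100 nM trametinib, an inhibitor of the kinases MEK1 and MEK2 that activate ERK. After 2 h, LPS, a bacterial ligand of TLR4, was added at 100 ng/ml for 12 h. There were 3 libraries per group and no culture without LPS, so the comparison shows what trametinib changed in LPS-treated cells, not what LPS induced. The vehicle libraries held 17732089, 17819451 and 17533137 counts, and the trametinib libraries 17645045, 19648467 and 17453778.

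The comparison addresses how blocking MEK alters the transcripts of macrophages responding to LPS. With trametinib, 10 of 13 tested genes of ERK pathway output and feedback fell, as did 16 of 19 of ribosome biogenesis and 10 of 16 of the integrated stress response and amino acid synthesis (camera adjusted p 4.58e-07, 5.67e-10 and 3.46e-07, and adjusted p 0.479 for each with an estimated correlation). Tnf, the gene of a central inflammatory cytokine, fell from 1054 ± 144 to 417 ± 17.4 CPM (SD, n = 3 per group). Nos2, which encodes inducible nitric oxide synthase, rose from 802 ± 77.1 to 2312 ± 544 CPM. Of 26 interferon-stimulated genes 15 rose, and of 17 genes of antigen presentation and costimulation 8 rose and 1 fell (camera adjusted p 0.00214 and 0.0231, and adjusted p 0.653 for each with an estimated correlation). These counts of risers moved with single libraries, to 3 in each list without trametinib replicate 1. Of 11286 genes tested with edgeR, 3869 (34.3%) changed, 1787 higher and 2082 lower with trametinib. At least 2-fold changes were seen in 745 genes, 332 higher and 413 lower, and at least 4-fold changes in 56 higher and 114 lower. The groups did not overlap in 5563 genes (49.3%), where chance gives 10%.

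Vehicle replicate 3 stood apart from the other vehicle libraries. On the first principal component, which held 68.8% of the variance and separated the groups, it lay at −16.2, against −39.3 and −38.1 for vehicle replicates 1 and 2 and 26.4 to 35.5 for the trametinib libraries. Of 96 genes at least 4-fold lower with trametinib than in vehicle replicates 1 and 2, 91 were lower in vehicle replicate 3 than in both of those, among them Dusp6 at 2.11 CPM against 14.5 and 17.1 in the other vehicle libraries. Choosing these genes by their values in vehicle replicates 1 and 2 favours lower values in vehicle replicate 3, so the count is descriptive. Without vehicle replicate 3 the count of changed genes was 4663, and without any other single library it lay between 2428 and 3632. Those changed were 2538 without vehicle replicate 1 and 2428 without trametinib replicate 1. Genes higher numbered 1131, 1165 and 1068 without vehicle replicate 1, vehicle replicate 2 and trametinib replicate 1, and genes lower 1360 without trametinib replicate 1.

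The sharpest falls included regulators that ERK activity itself induces. Dusp6, a phosphatase that inactivates ERK (ENSMUSG00000019960, mm10 chromosome 10, 99263231 to 99267489), had 603 counts in the vehicle libraries together and 2 in the trametinib libraries, a ratio of 297 with a 95% interval of 81.9 to 2459. Its adjusted p was 0.0149, and became 0.0584, 0.0605 and 0.0574 without trametinib replicates 1, 2 and 3, within a range of 2.63e-11 to 0.0605 over the alternatives. Spred2, an inhibitor of RAS signalling, fell from 16.2 ± 9.15 to 0.131 ± 0.0661 CPM (log2 fold change −6.88, SE 0.92, adjusted p 0.00374). Dusp4, a related nuclear phosphatase, fell from 35.5 ± 18.5 to 1.31 ± 0.509 CPM (adjusted p 0.00523). Klra2, a lectin-like receptor gene of the Ly49 family, fell by 5.44 on the log2 scale (SE 0.64, adjusted p 0.00238), and Cd33, a sialic acid-binding receptor gene, fell by 4.99 (SE 0.66, adjusted p 0.00490). Gpr84, a receptor for medium-chain fatty acids, fell from 80.3 ± 22.3 to 3.52 ± 0.501 CPM (adjusted p 0.000220). C5ar1, the receptor for the complement fragment C5a, fell from 104 ± 31.3 to 5.80 ± 2.47 CPM (adjusted p 0.00120). Ccl2, a chemokine that attracts monocytes, fell from 69.4 ± 50.8 to 1.31 ± 0.0955 CPM (log2 fold change −5.72, SE 1.15, adjusted p 0.0222). Ccl2 stood at 11.7 CPM in vehicle replicate 3. Its adjusted p was 0.0722 and 0.0677 without vehicle replicates 1 and 2, 0.0824, 0.0849 and 0.0765 without trametinib replicates 1, 2 and 3, and 0.0609 with limma-voom, in a range of 6.44e-10 to 0.0849 over the alternatives.

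The sharpest rises lay in genes of varied function. Diras2, a RAS-like GTPase, rose from 0.952 ± 0.486 to 17.1 ± 3.47 CPM (log2 fold change 4.15, SE 0.30, adjusted p 0.000220). Ubd, a ubiquitin-like modifier, rose from 1.56 ± 0.361 to 15.9 ± 3.52 CPM (adjusted p 0.000125), and Slc6a19, a transporter of neutral amino acids, from 2.78 ± 1.58 to 27.0 ± 3.32 CPM (adjusted p 0.000918). Dgat2, which makes triglycerides, rose 5.53-fold (adjusted p 0.00565), and Fbxo32, a ubiquitin ligase subunit, 5.51-fold (adjusted p 0.00245). Cacna1d, a calcium channel subunit, rose 5.25-fold (adjusted p 0.000104), and Nfil3, a basic leucine zipper transcription factor, rose from 17.4 ± 4.8 to 85.9 ± 8.87 CPM (adjusted p 0.000362). Dnase1l3, a secreted nuclease, rose 5.87-fold (adjusted p 0.00954). With the replicate block Dnase1l3 had an adjusted p of 0.0546, in a range of 8.33e-07 to 0.0546 over the alternatives.

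**Figure D1:**
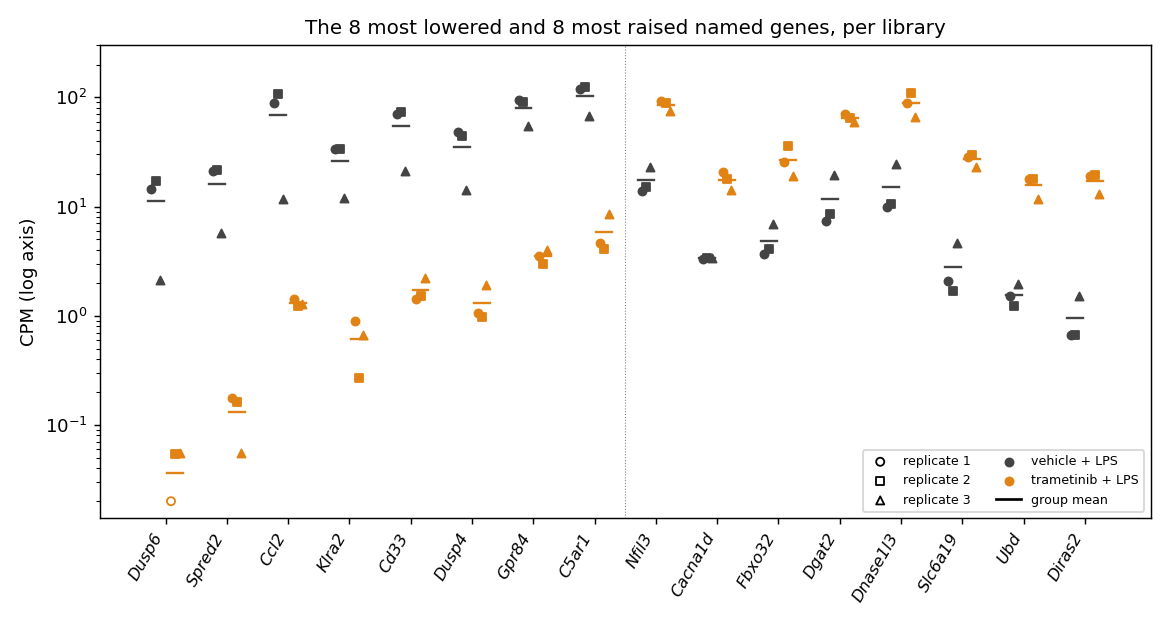
Expression in CPM on a log axis of the 8 genes with the lowest and the 8 with the highest log2 fold change under the naming rule, with 1 symbol per library (grey for vehicle, orange for trametinib, shapes for replicates 1 to 3) and horizontal lines at the group means. Gpr84 falls from a mean of 80.3 to 3.52 CPM and Nfil3 rises from 17.4 to 85.9; vehicle replicate 3 (triangles) lies at 2.11 CPM for Dusp6 against 14.5 and 17.1, and the open symbol at the lower edge marks a count of 0.

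The list of ERK pathway output and feedback had the lowest median of the pathway lists. Of its 13 tested members, 10 fell and none rose, and 3 did not pass (Dusp5, Spred3 and Epha4); 11 fell when adjusted over the list alone. The camera test gave an adjusted p of 4.58e-07, and the adjusted p was 0.479 with an estimated correlation. Spred1, another RAS pathway inhibitor, fell from 293 ± 93.9 to 46.4 ± 1.26 CPM (adjusted p 0.000768), and Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, fell by 3.17 on the log2 scale (adjusted p 0.00245). Spry1, of the same family, had 46 counts in the vehicle libraries and 2 in the trametinib libraries, a ratio of 22.7 (95% interval 5.93 to 193, adjusted p 0.00138). Spry4, with 0 or 1 counts per library, was not tested. Vehicle replicate 3 was also low in Spred2 (5.67 CPM against 21.3 and 21.7) and in the cell cycle activator Ccnd1 (1.68 CPM against a mean of 13.2 in the other vehicle libraries). Without vehicle replicate 3, 1 member of the list rose. Among immediate early and AP-1 genes, 7 of 13 fell, 1 rose and 5 did not pass, and 8 fell and 1 rose when adjusted over the list alone (camera adjusted p 0.00223). The adjusted p was 0.653 with an estimated correlation and 0.0522 with limma-voom, in a range of 8.09e-08 to 0.0522 over the alternatives. Egr1, a zinc finger transcription factor, fell by 6.23 on the log2 scale (SE 0.64, adjusted p 0.000645), the AP-1 subunit gene Fos fell by 2.72 (SE 0.45, adjusted p 0.00520) and Egr2 fell by 2.02 (adjusted p 0.00104). Atf3, a repressor induced by stress, rose 1.78-fold (adjusted p 0.000551), the only riser, and with the replicate block 2 members rose.

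Most genes of the RAS-RAF-MEK-ERK chain itself did not pass: 5 of 18 rose, 2 fell and 11 did not pass, with the same counts when adjusted over the list alone (camera adjusted p 0.628). Its median log2 fold change was −0.03, its mean 0.02 and the test pointed up. The adaptor gene Grb2 rose 1.39-fold (adjusted p 0.00430) and the kinase Map3k8, which activates MEK after LPS, 1.27-fold (adjusted p 0.00395). The drug target genes Map2k1 and Map2k2 had log2 fold changes of 0.01 each (SE 0.12 and 0.09, adjusted p 0.949 and 0.970), and the sign of both turned when single libraries were left out: Map2k1 had −0.09, −0.03 and −0.03 without vehicle replicate 3, trametinib replicate 1 and trametinib replicate 2, and Map2k2 −0.06 and −0.07 without vehicle replicate 3 and trametinib replicate 1. Mapk3, the gene of an ERK kinase, had a log2 fold change of 0.08 (adjusted p 0.438). Under the block 4 members fell. When libraries were left out, 3 members rose without vehicle replicate 1 or 2 or trametinib replicate 1 or 2. Members that fell were 4 without vehicle replicate 3 or trametinib replicate 3, 1 without vehicle replicate 1 and 0 without trametinib replicate 1 or 2.

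Cytokine genes moved in both directions. Of 14 proinflammatory cytokines, 6 fell, 2 rose and 6 did not pass, with the same counts adjusted over the list alone (camera adjusted p 0.0570, and 0.479 with an estimated correlation). This list passed with the replicate block (adjusted p 0.00892) and without vehicle replicates 1, 2 and 3 and trametinib replicates 1 and 2 (0.0327, 0.0143, 0.0114, 0.0447 and 0.0311), within a range of 0.00730 to 0.205 over the alternatives; without vehicle replicate 3, 4 members rose. Tnf fell by 1.34 on the log2 scale (SE 0.11, adjusted p 0.000178) and Tnfsf9, a costimulatory ligand, fell by 2.52 (SE 0.27, adjusted p 0.000871). Il1b fell from 375 ± 85.1 to 87.4 ± 60.6 CPM (log2 fold change −2.10, SE 0.56, adjusted p 0.0419). Trametinib replicate 3 stood at 156 CPM for Il1b against 66.7 and 39.9 in the other trametinib libraries, and without it the log2 fold change was −2.82. This call for Il1b was lost with the replicate block (adjusted p 0.125), without a filter on low counts (0.0939) and without vehicle replicates 1, 2 and 3 or trametinib replicates 1 and 2 (0.131, 0.133, 0.0930, 0.122 and 0.0538), in a range of 0.00302 to 0.133 over the alternatives. Il15, which sustains NK cells, rose from 119 ± 4.99 to 222 ± 34.0 CPM (adjusted p 0.000732). Il6 did not pass (log2 fold change −0.39, SE 0.57, adjusted p 0.641). With the replicate block the adjusted p of Il6 was 0.00665, and without vehicle replicate 3 its log2 fold change was 0.16, in a range of adjusted p of 0.00665 to 0.905 over the alternatives. Il12b did not pass (log2 fold change −0.83, adjusted p 0.123), and without vehicle replicate 3 it had an adjusted p of 0.0489 with a log2 fold change of −0.40, in a range of 0.0489 to 0.262.

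Chemokine genes split in the same way. Of 17 members, 6 fell, 3 rose and 8 did not pass, and 7 fell and 3 rose when adjusted over the list alone (camera adjusted p 0.0203, and adjusted p 0.653 with an estimated correlation). With the replicate block the list had an adjusted p of 0.0958, with 6 members higher, and with limma-voom 0.284, in a range of 8.09e-08 to 0.284 over the alternatives; 1 member rose without trametinib replicate 1 or 2. Ccl3, which attracts monocytes and other leukocytes, fell from 428 ± 109.9 to 76.4 ± 5.92 CPM (adjusted p 0.000308), Ccl9 fell by 1.17 on the log2 scale (adjusted p 0.000217) and Cxcl2, which attracts neutrophils, fell by 3.94 (SE 0.44, adjusted p 0.00206). Without trametinib replicate 3 the log2 fold change of Cxcl2 was −4.53. In vehicle replicate 3, Ccl7, another monocyte attractant, stood at 1.03 CPM against 34.2 and 35.9 in the other vehicle libraries. Ccl5, Cxcl9 and Cxcl16, chosen after their values were seen, rose with log2 fold changes of 0.38, 0.64 and 0.34 (adjusted p 0.00984, 0.00616 and 0.0122).

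Among 26 interferon-stimulated genes, 15 rose, none fell and 11 did not pass, and 17 rose when adjusted over the list alone (camera adjusted p 0.00214, and adjusted p 0.653 with an estimated correlation). Ifit1 and Ifit2, whose products bind viral RNA, rose 1.33-fold and 1.37-fold (adjusted p 0.00787 and 0.00954), and the GTPase gene Gbp3 1.36-fold (adjusted p 0.00446). The Ifit2 call was lost without trametinib replicate 2 (adjusted p 0.0539, in a range of 0.000408 to 0.0539 over the alternatives). Ifnb1, the gene of interferon beta, rose from 3.37 ± 1.53 to 6.83 ± 0.614 CPM (log2 fold change 1.01, SE 0.27, adjusted p 0.0229). For Ifnb1 the adjusted p was 0.0708 and 0.0722 without vehicle replicates 1 and 2 and 0.0681, 0.0604 and 0.0683 without trametinib replicates 1, 2 and 3, in a range of 9.08e-05 to 0.0722. Under the replicate block 23 members of the list rose. The count was 5 and 7 without vehicle replicates 1 and 2 and 3 without either trametinib replicate 1 or trametinib replicate 2.

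Of 17 antigen presentation and costimulation genes, 8 rose, 1 fell and 8 did not pass, and 10 rose and 1 fell when adjusted over the list alone (camera adjusted p 0.0231, and adjusted p 0.653 with an estimated correlation). H2-K1, a class I histocompatibility gene, rose 1.33-fold (adjusted p 0.00476), as did Cd86, a costimulatory ligand (1.33-fold, adjusted p 0.00578), whereas Cd80, its relative, was the member that fell (log2 fold change −0.95, adjusted p 0.00335). A fit with the replicate block had 13 members higher, and 4, 4, 3 and 4 rose without vehicle replicates 1 and 2 and trametinib replicates 1 and 2.

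Anti-inflammatory and negative regulators went both ways, with 5 of 16 higher, 7 lower and 4 not past, and 8 lower and 5 higher when adjusted over the list alone (camera adjusted p 0.336). Nfkbiz, a nuclear cofactor of NF-kappaB, fell by 1.48 on the log2 scale (adjusted p 0.000360) and Irak3, a brake on Toll-like receptor signalling, by 0.95 (adjusted p 0.000344), while Bcl3, a nuclear member of the IkappaB family, rose 1.83-fold (adjusted p 0.000677). Il10, an anti-inflammatory cytokine, fell from 9.13 ± 3.36 to 4.47 ± 0.430 CPM (log2 fold change −1.03, SE 0.27, adjusted p 0.0235). The Il10 call was lost without vehicle replicate 2 (adjusted p 0.0689) and without trametinib replicates 1, 2 and 3 (0.0824, 0.0841 and 0.0535), in a range of 0.000157 to 0.0841. Members that rose were 2 without vehicle replicate 2 or trametinib replicate 1. Among markers of alternative activation, 2 of 7 rose, none fell and 5 did not pass, with the same counts adjusted over the list alone (camera adjusted p 0.294). Klf4, a transcription factor of that programme, rose 3.00-fold (adjusted p 0.0102) and Pdcd1lg2, an inhibitory ligand of T cells, 1.67-fold (adjusted p 0.0212). For Pdcd1lg2 the adjusted p was 0.0672 without vehicle replicate 2 and 0.0878 and 0.0672 without trametinib replicates 1 and 2, in a range of 0.0164 to 0.0878, and 1 member rose in each of these settings. Without vehicle replicate 3, 1 member of the list fell.

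The nitric oxide and antimicrobial list held the rise of Nos2 (log2 fold change 1.53, SE 0.18, adjusted p 0.000965) beside more falls than rises: 3 of 15 rose, 7 fell and 5 did not pass, with the same counts adjusted over the list alone (camera adjusted p 0.511). Acod1, which makes itaconate, fell from 4613 ± 476 to 2379 ± 66.8 CPM (adjusted p 0.000268), and Slc11a1, a metal transporter of phagosomes, from 592 ± 116 to 305 ± 24.6 CPM (adjusted p 0.00192). Members that fell were 4 without vehicle replicate 1 or 2. In prostaglandin and eicosanoid synthesis, 4 of 11 fell, 1 rose and 6 did not pass, with the same counts adjusted over the list alone (camera adjusted p 0.459). The median log2 fold change of this list was 0.01, its mean −0.01 and the test pointed down. Ptgs2, the inducible cyclooxygenase, fell from 222 ± 31.3 to 112 ± 24.9 CPM (adjusted p 0.00477), Pla2g4a, which releases arachidonic acid, fell by 0.89 on the log2 scale (adjusted p 0.000447) and Ptges3 by 0.31 (adjusted p 0.00774). Members of it that rose were 2 with the replicate block, as without trametinib replicate 2, and 0 rose without vehicle replicate 1 or 2.

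Lists of receptors and sensors did not pass as sets, though single genes changed. Of 18 genes of Toll-like receptors and LPS sensing, 5 rose, 5 fell and 8 did not pass, and 5 rose and 8 fell when adjusted over the list alone (camera adjusted p 0.998; median log2 fold change 0.09, mean −0.03, test pointing down). Tlr4, the LPS receptor, fell from 56.8 ± 4.37 to 33.0 ± 3.85 CPM (adjusted p 0.000755), while Tlr9, a sensor of bacterial DNA, rose 1.56-fold (adjusted p 0.00110) and the adaptor Ticam1 1.44-fold (adjusted p 0.00134). The replicate block gave 8 fallen members, as without vehicle replicate 3, and 3 fell without vehicle replicate 1 or trametinib replicate 1 or 2. Members that rose were 2 without vehicle replicate 1 or 2 or trametinib replicate 1 or 2, and 3 without trametinib replicate 3. Of 12 inflammasome genes, 6 rose, 3 fell and 3 did not pass, with the same counts adjusted over the list alone (camera adjusted p 0.543; median log2 fold change 0.28, mean −0.13, test pointing up). Nlrp3, the sensor that LPS primes, fell from 266 ± 57.8 to 75.1 ± 9.37 CPM (adjusted p 0.000502), and Il18 and the DNA sensor Aim2 rose 1.62-fold and 1.44-fold (adjusted p 0.00126 and 0.00184). The list of growth factor and cytokine receptors also names the ligand gene Pdgfb. Of its 20 tested genes, 6 rose, 4 fell and 10 did not pass, and 6 rose and 5 fell when adjusted over the list alone. The camera test gave an adjusted p of 0.820 (median 0.04, mean −0.04, test pointing up). Ifngr1, a chain of the interferon gamma receptor, fell by 1.00 on the log2 scale (adjusted p 0.000280), and Ifnar1 and Csf2ra, chains of the receptors for type I interferon and GM-CSF, by 0.55 each (adjusted p 0.00186 and 0.00305). Without vehicle replicate 3, 7 members of this list fell.

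Genes in the list of phagocytic receptors mostly fell where they passed, and genes in the matrix list went both ways. The list of scavenger and phagocytic receptors also holds the complement genes C1qa, C1qb and C1qc. Of its 21 genes, 10 fell, 1 rose and 10 did not pass, with the same counts adjusted over the list alone (camera adjusted p 0.0570, and 0.653 with an estimated correlation). The list passed with the replicate block (adjusted p 0.0239, with 3 members higher) and without vehicle replicate 3 (0.00155) or trametinib replicate 2 (0.0134), in a range of 0.00155 to 0.145 over the alternatives. Msr1, a scavenger receptor for modified lipoproteins, fell from 745 ± 332 to 53.5 ± 1.92 CPM (log2 fold change −3.80, SE 0.41, adjusted p 0.00186), with 363 CPM in vehicle replicate 3 against 906 and 965 in the others, and Clec4e, a receptor for mycobacterial glycolipid, from 3595 ± 221 to 2600.2 ± 41.7 CPM (adjusted p 0.00172). Mertk, a receptor for the uptake of apoptotic cells, rose 2.22-fold (adjusted p 0.000412) and was the member that rose. Of 15 genes of matrix proteases and the plasminogen system, 3 rose, 4 fell and 8 did not pass, and 3 rose and 6 fell when adjusted over the list alone (camera adjusted p 0.511; median log2 fold change −0.36, mean −0.48, test pointing up). Vegfa, an angiogenic growth factor, rose 2.33-fold (adjusted p 9.80e-05), Thbs1, a matrix glycoprotein, 3.82-fold (adjusted p 0.000447) and Mmp19 1.65-fold (adjusted p 0.00365), the members with the smallest p, all of which rose. In the fit with the replicate block 5 of these rose and 7 fell. Those that fell were 7 without vehicle replicate 3, 2 without trametinib replicate 1 and 1 without vehicle replicate 2, trametinib replicate 2 or trametinib replicate 3.

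Members of the metabolic lists moved in different directions. Of 19 glycolysis genes, 7 rose, 1 fell and 11 did not pass, with the same counts adjusted over the list alone (camera adjusted p 0.0231, and adjusted p 0.653 with an estimated correlation). Without vehicle replicate 3 the adjusted p was 0.113, with 3 members lower, in a range of 0.00233 to 0.113, and with the replicate block 2 members fell. Pfkl, a phosphofructokinase, rose 1.71-fold (adjusted p 0.000426), the lactate exporter Slc16a3 1.56-fold (adjusted p 0.000412) and Hif1a, a regulator of glycolytic genes, 1.85-fold (adjusted p 0.000535). Of 22 genes of cholesterol synthesis, none rose, 8 fell and 14 did not pass, and 9 fell when adjusted over the list alone (camera adjusted p 0.0268, and adjusted p 0.653 with an estimated correlation). That call was lost without vehicle replicate 3 (adjusted p 0.166) and trametinib replicate 2 (0.0556), in a range of 0.00279 to 0.166, and 5 genes fell without trametinib replicate 1 or 2. Blocking on the replicate gave 1 member that rose, as without vehicle replicate 3. Sqle, which forms squalene epoxide, fell by 1.05 on the log2 scale (adjusted p 0.00800), Srebf2, the main transcription factor of the pathway, by 0.69 (adjusted p 0.00425) and Idi1 by 0.62 (adjusted p 0.00525). Of 14 genes of cholesterol efflux and LXR targets, 4 rose, 2 fell and 8 did not pass, and 4 rose and 3 fell when adjusted over the list alone (camera adjusted p 0.340). The exporters Abcg1 and Abca1 rose 2.75-fold and 1.95-fold (adjusted p 0.000104 and 0.00107), and Fasn, the fatty acid synthase, fell by 0.90 (adjusted p 0.00374). In this list 2 members rose without vehicle replicate 1 or 2 or trametinib replicate 2.

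Of 24 lysosome and TFEB target genes, 11 rose, 2 fell and 11 did not pass, with the same counts adjusted over the list alone (camera adjusted p 0.0268, and adjusted p 0.653 with an estimated correlation). Ctsk, a lysosomal protease, rose from 39.4 ± 4.02 to 93.4 ± 18.2 CPM (adjusted p 0.00115), Tfeb, the transcription factor of lysosomal genes, 1.71-fold (adjusted p 0.00152) and Gla, a lysosomal galactosidase, 1.42-fold (adjusted p 0.00653). The members that fell were the related factors Tfe3 and Mitf (log2 fold change −0.41 and −0.31, adjusted p 0.0120 and 0.00739), named after their values were seen. The list's call was lost without vehicle replicate 3 (adjusted p 0.166) and trametinib replicate 1 (0.0560), in a range of 0.00212 to 0.166 over the alternatives. With the replicate block 17 members rose, and 3, 5, 4 and 4 rose without vehicle replicates 1 and 2 and trametinib replicates 1 and 2.

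In ribosome biogenesis and MYC targets, 16 of 19 fell, none rose and 3 did not pass, and 16 fell when adjusted over the list alone (camera adjusted p 5.67e-10, and adjusted p 0.479 with an estimated correlation). Nop56, a core protein of box C/D snoRNPs, fell from 32.3 ± 2.31 to 15.9 ± 1.5 CPM (adjusted p 0.000290), Rrs1 fell by 1.01 on the log2 scale (adjusted p 0.000460) and Wdr12 by 1.07 (adjusted p 0.000502), both factors of large-subunit assembly. In the integrated stress response and amino acid synthesis list, 10 of 16 fell, none rose and 6 did not pass, with the same counts adjusted over the list alone (camera adjusted p 3.46e-07, and adjusted p 0.479 with an estimated correlation). Asns, the asparagine synthetase, fell from 106 ± 8.91 to 42.8 ± 0.890 CPM (log2 fold change −1.32, SE 0.08, adjusted p 9.80e-05), Aldh18a1, of proline synthesis, by 1.08 on the log2 scale (adjusted p 0.000163) and Phgdh, of serine synthesis, from 146 ± 4.68 to 87.5 ± 5.05 CPM (adjusted p 0.000268). Of 12 NRF2 targets, 2 fell, none rose and 10 did not pass, with the same counts adjusted over the list alone (camera adjusted p 0.211). Gsr, the glutathione reductase, fell by 1.65 on the log2 scale (adjusted p 0.000639) and Txnrd1, the thioredoxin reductase, by 0.49 (adjusted p 0.00350). Blocking on the replicate gave 1 NRF2 target that rose, and without vehicle replicate 3, 4 fell.

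Genes of the BCL2 family, which set the threshold of apoptosis, moved both ways. Of its members, 5 of 15 rose, 6 fell and 4 did not pass, and 6 rose and 6 fell when adjusted over the list alone (camera adjusted p 0.449). Bcl2a1b and Bcl2a1a, which oppose apoptosis, fell by 1.22 and 0.97 on the log2 scale (adjusted p 0.000178 and 0.000595), and Bbc3 (PUMA), which promotes it, rose 2.01-fold (adjusted p 0.00177). Other members, named after their values were seen, included the antiapoptotic Bcl2 and Bcl2l1, with log2 fold changes of −4.32 and −2.15 (adjusted p 0.00786 and 0.0193), and the proapoptotic Bcl2l11 (BIM) and Bmf, with 1.96 and 1.54 (adjusted p 0.0262 and 0.0230). Bid, which is proapoptotic, fell (log2 fold change −0.45, adjusted p 0.00316), and Mcl1 had 0.19 (adjusted p 0.0815). Members that rose were 2 without vehicle replicate 2 or any of trametinib replicates 1, 2 and 3, and 3 without vehicle replicate 1. Of 17 cell cycle genes, 2 rose, 1 fell and 14 did not pass, with the same counts adjusted over the list alone (camera adjusted p 0.470). Ccne1, a cyclin of S phase entry, rose 2.23-fold (adjusted p 0.0117, and 0.0503 without a filter on low counts, in a range of 9.43e-07 to 0.0503), and the replication licensing gene Mcm3 fell by 0.60 on the log2 scale (adjusted p 0.00198). Mcm7 rose 1.36-fold (adjusted p 0.0301), with an adjusted p of 0.0715 with DESeq2, 0.118 and 0.0560 without vehicle replicates 1 and 2 and 0.0684, 0.0776 and 0.0708 without trametinib replicates 1, 2 and 3, in a range of 0.0249 to 0.118. Without vehicle replicate 3, 5 cell cycle genes rose and 2 fell, 1 rose without trametinib replicate 1 or 2, and with the replicate block 2 fell.

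**Figure D2:**
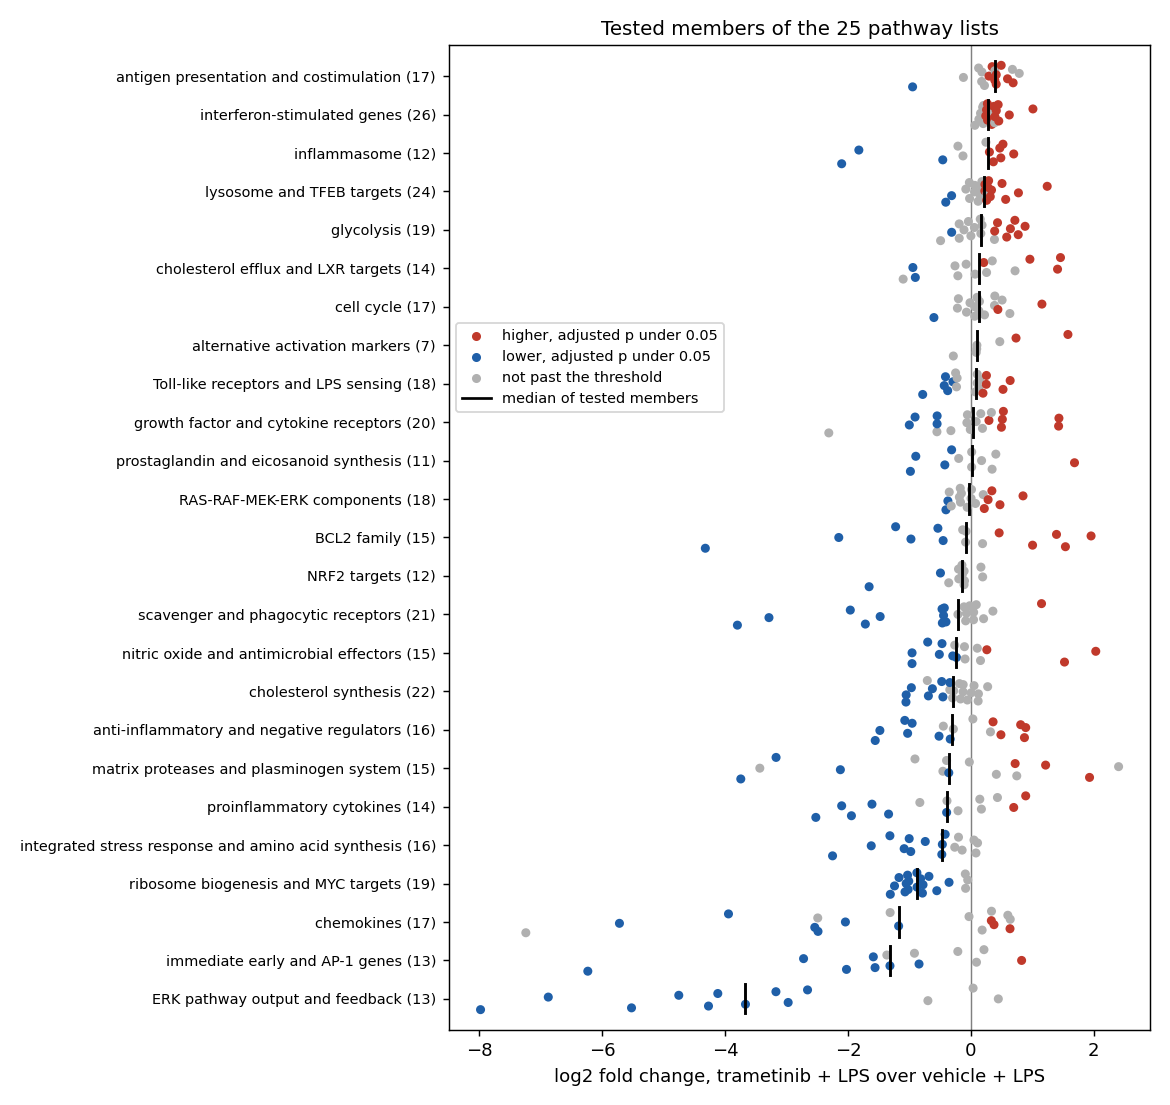
Log2 fold change, trametinib over vehicle, of every tested member of the 25 pathway lists, with 1 point per gene, red for higher, blue for lower and grey for not past the threshold, a black bar at each list's median and the number of tested members in brackets; the fitted values of Dusp6 and Spry1 rest on 2 counts in the trametinib libraries. Ribosome biogenesis members lie below 0, with 16 of 19 past the threshold, and 15 of 26 interferon-stimulated genes lie above 0 and past it.

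Of the 25 lists, 10 passed with camera, 4 higher and 6 lower, and none passed with an estimated correlation (adjusted p 0.479 to 0.998, with 1 at an unadjusted p under 0.05), while 13 passed with fry, which does not compare a list with other genes. Where a pathway list had no member called in a direction, DESeq2, limma-voom and an unadjusted p under 0.05 with edgeR gave 0 members too.

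Macrophage markers were abundant in both groups. All 10 macrophage markers were tested, and Lyz2, the lysozyme gene of myeloid cells, stood at 10179 CPM with vehicle and 9724 with trametinib (log2 fold change −0.07, adjusted p 0.559). Mertk and Cd14 rose, the latter with a log2 fold change of 0.25 (adjusted p 0.0214), and Adgre1 (F4/80) and Itgam (CD11b) fell by 0.91 and 1.16 on the log2 scale (adjusted p 0.000502 and 0.0437), while 6 did not pass. Of the markers of resident large peritoneal macrophages, 3 of 9 were tested and none passed, and of eosinophil markers 1 of 8 was tested and did not pass. Of neutrophil markers 5 of 11 were tested and 1 rose (Csf3r, log2 fold change 0.53, adjusted p 0.00355). Of mast cell markers 2 of 9 were tested and 1 rose (Hdc, 1.62, adjusted p 0.000463), or 2 when adjusted over the list alone. Of B cell markers 1 of 10 was tested and rose (Bank1, 0.85, adjusted p 0.0449). Of markers of T and NK cells 3 of 12, and of dendritic cells 4 of 10, were tested and none passed, and none of the 11 fibroblast and mesothelial markers reached the level for a test. At an unadjusted p under 0.05, 1 resident macrophage marker (Vsig4) and 1 dendritic cell marker (Ccr7) were higher, and 0 of the tested eosinophil, T and NK cell markers passed. These single genes were named after their values were seen.

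No RNA quality measure passed its test. Of nuclear-retained RNAs 3 of 5 were tested and none passed, and none of 13 mitochondrially encoded mRNAs passed with edgeR, and 0 of either list had an unadjusted p under 0.05. Mitochondrial mRNAs made up 0.717%, 0.871% and 0.796% of counts in the vehicle libraries and 0.763%, 1.76% and 0.840% in the trametinib libraries. The means, 0.794% ± 0.0771 and 1.12% ± 0.552 (SD, n = 3 per group), differed by 0.325 percentage points (exact permutation test, two-sided, p = 0.5; 3 libraries against 3 cannot go below 0.1). Without trametinib replicate 2 the difference was 0.00713 percentage points. Some of these mRNAs varied strongly between libraries, mt-Co3 for instance from 20 counts in vehicle replicate 1 to 25059 in trametinib replicate 2. The mitochondrial values are therefore a weak measure of RNA quality.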

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

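The alternatives for the gene families were chosen after the data were seen, and the others were planned. No gene called in the full comparison was called in the opposite direction in any alternative, and with the replicate block 3839 of the 3869 changed genes were shared among 4837. Changed genes ranged from 2428 to 4663 when single libraries were left out, genes higher from 1068 to 2210 and genes lower from 1360 to 2453, and fewer samples enter these fits. Under the other settings changed genes numbered 3518 (DESeq2) to 3897 (median-ratio size factors), apart from the block. Lists past the threshold were 10 with camera, 0 with an estimated correlation and 13 with fry. The sign of the list test turned for Toll-like receptors (adjusted p 0.985 with median-ratio size factors, 0.944 with the filter of 1 CPM, 0.939 with DESeq2, 0.953 with limma-voom, 0.982 with the replicate block, 0.838 to 0.999 without single libraries), for matrix proteases (0.757 with the replicate block, 0.158 to 0.532 without single libraries) and for growth factor and cytokine receptors (0.859 with no filter, 0.501 to 0.988 without single libraries), and the cause was not tested. Of 1285 alternative values for 99 named genes, 1279 kept their direction; the 6 others belong to Map2k1 (log2 fold change −0.0916 to 0.104 without single libraries), Map2k2 (−0.0742 to 0.0635) and Il6 (−0.962 to 0.162), and 37 values in 10 genes lost a call while 3 gained one. The replicate block changed no other call of a named gene or list than those given with the results. Of the 10 called lists, 5 passed in all 13 settings of the gene-level test (ERK output, interferon-stimulated genes, antigen presentation, ribosome biogenesis and integrated stress response). In simulated data at this depth 47.9% of 1.5-fold changes were recovered, and small changes can be missed. Only 200 genes were given these folds there, against 3869 called in the data, which makes the adjusted threshold stricter in the simulation. The share recovered therefore does not give the power of the real comparison.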

Other observations

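The tests of mixing, of GC content and length, of a general mitochondrial rise and of other splits were chosen only after the result was seen, as were the gene families, while the tests of a nuclear copy and of AU-rich elements were fixed before their results were seen.

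Some gene families of protein synthesis and ribosome assembly had many members that fell with trametinib, while genes with Rpl and Rps symbols mostly did not pass. Families were sets of at least 10 tested genes whose symbols share the letters before the first digit. The cytosolic synthetases were instead listed by hand after the data were seen, and 19 of the 20 listed were tested. The adjustment over the families does not cover that choice. The families were not tested against each other. Of 19 cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, 16 fell and 1 rose (camera adjusted p 5.66e-10 over 135 families, 8 of which passed and 7 of which are described, and adjusted p 0.775 with an estimated correlation, as for each of the 8). Rars and Farsb fell by 1.05 each on the log2 scale (adjusted p 0.000141 and 0.000246) and Yars by 0.94 (adjusted p 0.000178), whereas Wars, which interferon induces, rose (log2 fold change 0.40, adjusted p 0.0201). Genes with Eif symbols include inhibitors of translation initiation beside initiation factors. Of 53 such genes, 26 fell and 2 rose (camera adjusted p 0.00152, and adjusted p 0.775 with an estimated correlation). Log2 fold changes were −1.48 for Eif2b3 and −1.18 for the cap-binding Eif4e (adjusted p 0.000375 and 0.000983). The inhibitor gene Eif4ebp1 was also among those that fell (−0.56, adjusted p 0.0118). Of 10 Utp genes, of the small ribosomal subunit processome, 8 fell (camera adjusted p 0.000346, and adjusted p 0.775 with an estimated correlation), among them Utp20 (−1.37, adjusted p 0.000447). Of 50 Rpl genes, of the large ribosomal subunit, 0 passed with edgeR and 2 had an unadjusted p under 0.05 (camera adjusted p 0.989). Of 44 genes with Rps symbols, which include kinases beside proteins of the small subunit, 3 fell (camera adjusted p 0.989, with a median log2 fold change of −0.01 and the test pointing up). Among genes of mitochondrial ribosomal proteins, 18 of 48 Mrpl genes fell and 1 rose, and 11 of 29 Mrps genes fell and 0 rose (camera adjusted p 0.124 and 0.119).

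Other families moved in either direction. Of 11 guanylate-binding protein genes (Gbp), close paralogs that interferon induces, 10 rose, among them Gbp4 (log2 fold change 1.12, adjusted p 0.000360; camera adjusted p 0.000346, and adjusted p 0.775 with an estimated correlation). Of 10 tested histone genes with Hist symbols, 7 rose (camera adjusted p 0.00119, and adjusted p 0.775 with an estimated correlation), and 5 rose without vehicle replicate 3. Hist1h2bc had a log2 fold change of 0.98 (adjusted p 0.000619). Hist1h3d, Hist1h2bg and Hist1h2ac, which also rose, had means under 1 CPM in both groups. Dock genes had 7 of 11 lower and 1 higher, with Dock4 at −1.94 (adjusted p 0.000299; camera adjusted p 0.0158, and adjusted p 0.775 with an estimated correlation). Ccl chemokines had 4 of 11 lower and 1 higher (camera adjusted p 0.0244, and adjusted p 0.775 with an estimated correlation). The leading direction of each family named here held with median-ratio size factors, with the replicate block and without vehicle replicate 3. These were the only alternatives run for the families. Leaving out trametinib replicate 1 or 2, which cut the changed genes to 2428 and 2646, was not among them. Dock genes higher were 2 with the block and 3 without vehicle replicate 3, and Ccl genes higher were 3 with the block.

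Vehicle replicate 3 lay toward the trametinib libraries. RNA of a trametinib culture mixed into it would leave 1 common share of each strongly lowered gene, yet over 96 genes at least 4-fold lower than in vehicle replicates 1 and 2 the spread of the log2 ratio of this library to those was 4.10 times that between replicates 1 and 2 (interquartile range 0.788 against 0.192). Ccl7 kept 2.93% of its level and Dusp6 13.4%, while Marco kept 139%, and the median was 51.5%. This range argues against a single mixed-in share as the only difference of this library. Vehicle replicates 1 and 2 were the closest pair within a group, with a chi-square per gene of 5.98 against 12.9 to 28.1 for the other pairs. Their spread is thus a narrow yardstick, and mixing beside other differences between libraries was not excluded. Removing a trend on GC content and length kept 98.9% of the slope of its deviation on the trametinib effect, which argues against that trend as the whole cause. No biological explanation was tested, since the design names none, and a difference between animals, timing or culture stays open.

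The mRNAs mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8 were highest in replicate 2 of both groups, with mt-Co2 at 60, 1980 and 116 counts in the vehicle libraries and 51, 40144 and 107 in the trametinib libraries, and so were mt-Nd4l (0, 1162 and 10, then 0, 2065 and 649) and mt-Nd3 (0, 449 and 6, then 0, 814 and 212). In trametinib replicate 2 the median log2 ratio to the other trametinib libraries was 8.78 over the first 4 and 0.0481 over the other 9 mitochondrial mRNAs, of which 4 were higher (mt-Nd4l 4.70, mt-Nd3 4.16, mt-Nd4 1.06 and mt-Co1 1.03) and 5 lay between −0.21 and 0.05, which argues against a rise of all mitochondrial RNA by the same factor, though not against a rise of part of it. At a minimum of 98% identity over 90% of the length, 3 of the 4 have an annotated nuclear copy on chromosome 1, 100% identical (Gm28661 at 24614885 to 24615565 for mt-Co2, Gm28437 at 24613189 to 24613971 for mt-Co3 and Gm10925 at 24613974 to 24614651 for mt-Atp6), as have mt-Nd4l (Gm10222, 24612407 to 24612700) and, at 99.7% identity, mt-Nd3 (Gm28438, 24612775 to 24613119), and 0 of 5 mitochondrial mRNAs that varied less than 2-fold have one, though mt-Cytb and mt-Nd6 among these have copies of 92.9% and 93.6% identity. Going the other way, mt-Nd4 was raised with no annotated copy and mt-Co1 with one of 97.6% identity, and no copy of mt-Atp8 is annotated, but 233 bases lie between those of mt-Atp6 and mt-Co2, so reads shared with a nuclear copy and a change in these mRNAs cannot be told apart without the genome sequence and the reads. The nuclear copies are not among the genes counted. In vehicle replicate 1, mt-Co2 had 60 counts where mt-Co1 had 68366, so which libraries deviate is not settled. No biological explanation was tested, since replicate numbers name no condition.

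Several inflammatory mRNAs that fell carry AU-rich elements, which shorten the life of an mRNA, among them Tnf with 8 motifs in its 3′ UTR, Cxcl2 with 7 and Ptgs2 with 6. Ccl3, which also fell, and Il6, which did not pass, have 1 each. Over 1158 genes with at least 2 such motifs the median log2 fold change was −0.0437. In 10000 random gene sets matched on 3′ UTR length, AT content and expression, the medians had a mean of −0.0108 and a central 95% of −0.0320 to 0.00751. Drawing such sets treats genes as independent, so this range may be too narrow. Whether the shift exceeds the spread between the 6 libraries was not tested. The hypothesis that mRNAs with AU-rich elements fall somewhat more under trametinib predicts a lower median, but the shift is small. Of the 1158 genes, 166 rose while 263 fell. Nos2, with 2 motifs, and Zfp36, with 3, which encodes a protein that binds them, rose. Levels alone cannot separate decay from synthesis.

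Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real one, namely the real split itself, with 3869 genes by edgeR and 0 as the highest of the others (5105 genes at an unadjusted p under 0.05 in the real split and 28 to 626 in the others). Each of the other splits mixes vehicle and trametinib libraries within its groups, so the trametinib effect adds to their spread and lowers the calls. The 0 therefore gives no evidence against chance. The splits are also too few for a share under 0.05. Of the 10, 4 part all 3 pairs of the same number, the real one included, and the other 6 part 1 pair.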
